A study of Homo sapiens with 6 samples.

How the data were processed

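Guide RNAs integrated in the genome of H358 cells were counted by sequencing after a pooled CRISPR-Cas9 knockout screen of human kinases. The series holds 6 samples. These are a baseline (T0) library of the parental line, a baseline library of the sotorasib-resistant line, and 2 libraries of each line after 2 weeks of further culture (T1). Per the labels' protocols, cells were transduced at a multiplicity of infection of 0.3, selected with puromycin, and partly harvested as the baseline, and the guides were amplified from genomic DNA. The submitters' processing notes name cutadapt, MAGeCK and edgeR with no version, role or order. The guide reference, the mismatch settings and any filter are not given in the sources used here, and no molecular identifier is mentioned.

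The deposited table gives whole-number read counts per guide, not normalized, as deposited by the authors, with the gene each guide targets. It holds 3149 guides, of which 3049 target 763 kinase genes and 100 are non-targeting controls. A column was used only where its name matched the labels of a single sample. This held for the 4 T1 libraries. The names of 2 further columns match a baseline library of either line, so neither column was used. All planned comparisons against T0 (each line against its own baseline, the difference of dropout between the lines, and baseline against baseline) were therefore not made, and the fit and the count filter planned over all 6 libraries used the 4 T1 libraries. A gene's values at T1 then include how often its guides were present at transduction, which is not corrected for.

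Guides with a mean count below 10 over the 4 libraries were left out, which removed 3 guides and kept 3146. The analysis used R 4.3.3. Counts were scaled with TMM factors and tested with the quasi-likelihood test of edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest), resistant T1 against parental T1, with Benjamini-Hochberg adjustment over the guides. Values per guide are given as CPM, the counts relative to the TMM-scaled library size. For each gene named, the median log2 fold change of its guides is reported, and the range over guides is given for EGFR and a few others. Genes were tested by robust rank aggregation in the manner of MAGeCK, written for this work. Guides were ranked by the signed edgeR p among all guides, with non-targeting guides included in the ranks. The score of a gene was the smallest beta probability over its guides within the top 0.25 of ranks, and its null came from 1000000 seeded draws of uniform ranks for the same number of guides. Each direction was tested one-sided and adjusted by Benjamini-Hochberg over the 763 genes, with 0.05 as the threshold. The guides of a gene are its repeats in this test, so a gene is compared with the rest of the library. In total 757 genes were tested with 4 guides and 6 with fewer.

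Before the data were examined, 14 kinase lists were fixed: core-essential kinases, tissue-restricted kinases that lung epithelium is not known to use, epithelial receptor tyrosine kinases, the RAF-MEK-ERK cascade, the PI3K-AKT-mTOR pathway, SRC-family and focal adhesion kinases, LKB1-AMPK and related kinases, Hippo pathway kinases, stress-activated MAPK cascades, cell-cycle and mitotic kinases, DNA damage kinases, transcription and splicing kinases, TGF-beta and BMP receptor kinases, and nucleotide and cofactor kinases. Lists were tested with camera of limma 3.58.1 on the guides' log2 CPM, with a preset correlation of 0.01 between guides and adjustment over the 14 lists. The lists overlap, and PLK1, for example, is in more than 1 of them. The genes named in the text were also set by a rule fixed at that time. Up to 10 depleted and 6 enriched genes past the threshold with the same sign in both replicate pairs were to be named. Where fewer than 5 passed in a direction, the 5 with the smallest p were named instead. A fixed panel of 25 kinases and up to 4 members per list in order of p were added. Some of the genes that this rule names are not reported here and not drawn.

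The sequencing depth was 1705247 and 3909718 reads in the parental libraries and 1772336 and 2239313 reads in the resistant libraries. The exact intervals on shares of called guides count guides as if independent and do not cover the spread between cultures. Reads are not cells either, since PCR copies of a guide are not separate cells. The labels do not say whether the replicates came from separate transductions. The guide p-values of edgeR rest on the spread between these cultures, pooled over guides, and that spread may be technical. Rank aggregation and camera compare the guides of a gene or list with the other guides. Their p-values do not measure how well a result repeats between cultures. Within-line replicates were not copies of each other. A chi-square of their guide counts was 46.0 per degree of freedom for the parental and 50.9 for the resistant pair. Samples with the same replicate number did not deviate together (r = 0.01 across guides), so the numbers were not taken to pair the libraries.

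The whole procedure was tested on simulated data made from the real guides, library sizes and dispersion, with 200 of 763 genes changed. With replicate noise alone, 40% of genes changed 2-fold and 100% of those changed 4-fold were recovered, and 1 of 563 unchanged genes was called. When each guide also received a line difference drawn from the non-targeting guides, 6% of 2-fold and 70% of 4-fold changes were recovered, and again 1 of 563 unchanged genes was called. The differences drawn already hold replicate noise, which the simulation adds again, and this may make these shares too low. In both simulations all guides of a changed gene received the same change, whereas real guides of a gene vary. This may make the shares too high, so they do not show how sensitive the screen was. The simulation with line differences called 15 of 100 non-targeting guides, against 10 of 100 in the real data. With guide labels shuffled across genes, 5 of 100 shuffles called any gene, and at most 2 genes.

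The alternatives tried were other scalings (DESeq2 size factors, total counts, the tissue-restricted guides, the non-targeting guides), other count filters (none, or a mean of 100 or more), the test of DESeq2 1.42.0, the replicate number as a block, leaving out each library, summed counts per gene, camera per gene, an adjusted p under 0.10, and camera with an estimated correlation, fry and shuffled genes for the lists. The scaling on non-targeting guides and the shuffled genes were added after seeing the data. Gene symbols are those of the deposited table. Of 763 symbols, 745 matched a current symbol and 17 an older symbol of the NCBI gene table of assembly GRCh38.p14, and 1 matched none. No genome build is named for the guides, so no coordinates are given.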

Results

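Guide abundance was measured in 2 parental and 2 sotorasib-resistant libraries of H358, an established human non-small-cell lung cancer line. Sotorasib is a covalent small-molecule cancer drug. The resistant line had been selected on rising doses and kept at 400 nM. After transduction with a kinome-wide knockout library, the parental cells were cultured for 2 weeks with the solvent DMSO and the resistant cells for 2 weeks with sotorasib. Line and drug therefore changed together. Depth averaged 542 and 1242 reads per guide in parental replicates 1 and 2 and 563 and 711 in resistant replicates 1 and 2. Log2 CPM of replicates correlated across guides at r = 0.84 in parental and r = 0.74 in resistant cells, and at r = 0.62 to 0.63 between lines. Guides are not independent replicates in these correlations.

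Guides against kinases that most cells need were scarce in both lines. Relative to the median of the 100 non-targeting guides in the same library, the median guide of the 38 core-essential kinases stood at -1.42 ± 0.03 on the log2 scale in parental cells (SD, n = 2) and at -1.05 ± 0.01 in resistant cells (SD, n = 2). The 45 measured tissue-restricted kinases stood at -0.48 ± 0.07 and -0.42 ± 0.02 (SD, n = 2 each). Guides against CDC7, the kinase that fires replication origins, had the lowest parental level of the genes named here, -5.52 ± 1.10, against -3.02 ± 0.45 in resistant cells (SD, n = 2 each). CDK1, the mitotic cyclin-dependent kinase, stood at -4.74 ± 1.95 and -3.03 ± 0.08, and PLK1, a mitotic kinase, at -3.10 ± 0.23 and -2.36 ± 0.50. Fewer guides were absent from the resistant libraries at T1, and whether the absent guides had been present at transduction was not tested. Counts of 0 were found for 22 and 26 of 3149 guides in parental replicates 1 and 2 and for 4 and 5 in resistant replicates 1 and 2. The level of a guide at T1 also depends on its share at transduction. Some CDC7 and CDK1 guides had parental counts at or near 0, where log2 levels are imprecise.

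The comparison of the resistant with the parental line asked which kinase knockouts were tolerated differently by cells that grow under sotorasib. Of 763 genes, 2 passed the threshold, both with guides that rose in the resistant line, and EGFR, the epidermal growth factor receptor, was among them. The median EGFR guide was 5.41-fold more abundant in resistant cells (log2 fold change 2.44, range over 4 guides -0.01 to 3.41, rank aggregation adjusted p = 0.00992). Of its 4 guides, 3 also passed edgeR's test singly, and the remaining guide had a log2 fold change of -0.01 ± 0.51 (SE). Averaged over its guides, EGFR rose from 134 ± 17.2 CPM per guide in parental to 701 ± 3.02 in resistant cells (SD, n = 2 each).

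**Figure D1:**
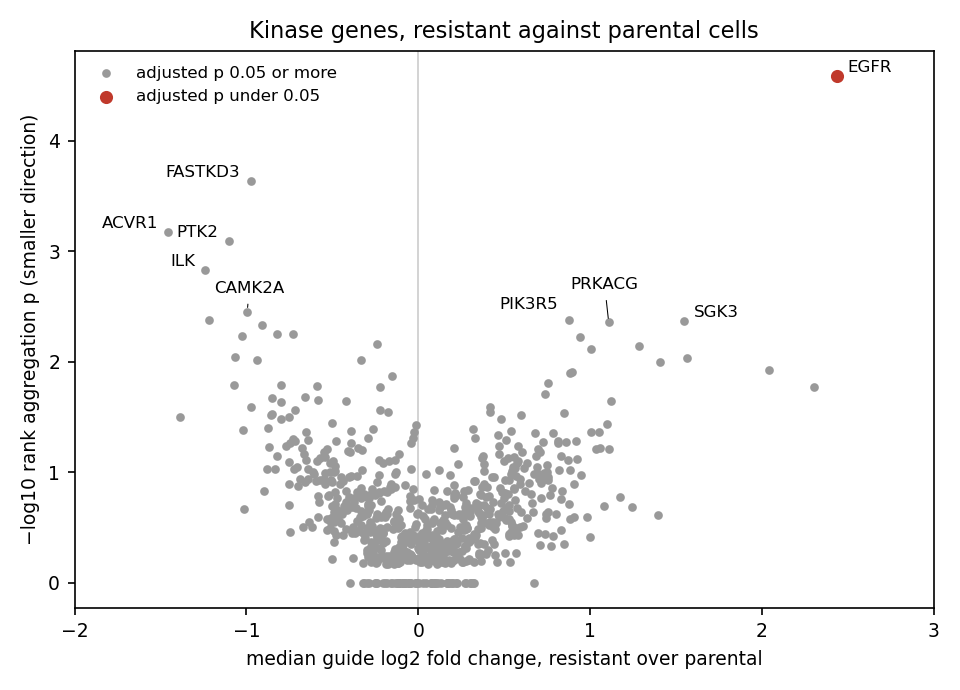
Points are kinase genes. The x axis is the median guide log2 fold change of resistant over parental cells, and the y axis is the -log10 of the smaller one-sided rank aggregation p. EGFR (log2 2.44), in red, lies past the adjusted threshold, and genes that do not pass are grey.

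Set against the median non-targeting guide in the same libraries, the median EGFR guide moved from -1.58 ± 0.39 in parental to 0.48 ± 0.05 in resistant cells (log2, SD, n = 2 each). EGFR passed the threshold under all of the 12 other settings of scaling, filter, guide test, block and left-out library, with medians of 2.28 to 2.54. It did not pass with camera applied to each gene's guides, where the adjusted p was 0.164.

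In the RAF-MEK-ERK list, BRAF, ARAF and MAP2K1, which encodes MEK1, did not pass, whether adjusted over all genes or adjusted over the list alone. Median log2 fold changes were -0.29 for BRAF, 0.10 for ARAF and -0.04 for MAP2K1, but the sign of ARAF rested on resistant replicate 1 (-0.18 without it), and MAP2K1 changed sign under several settings, for example 0.37 without parental replicate 1. RPS6KA3 and RPS6KA2, of the RSK family, stood at 0.48 and 0.71 and did not pass. The list as a whole had a camera adjusted p of 0.567 (0.683 with an estimated correlation). Of 25 epithelial receptor tyrosine kinases, EGFR rose, none fell and 24 did not pass, by both adjustments. The partners ERBB2 and ERBB3 stood at 0.70 and 0.57, and IGF1R at 0.17. MET stood at -0.80, RET at -0.85, ROS1 at -0.72 and FGFR1 at -0.37. The camera adjusted p of this list was 0.937.

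**Figure D2:**
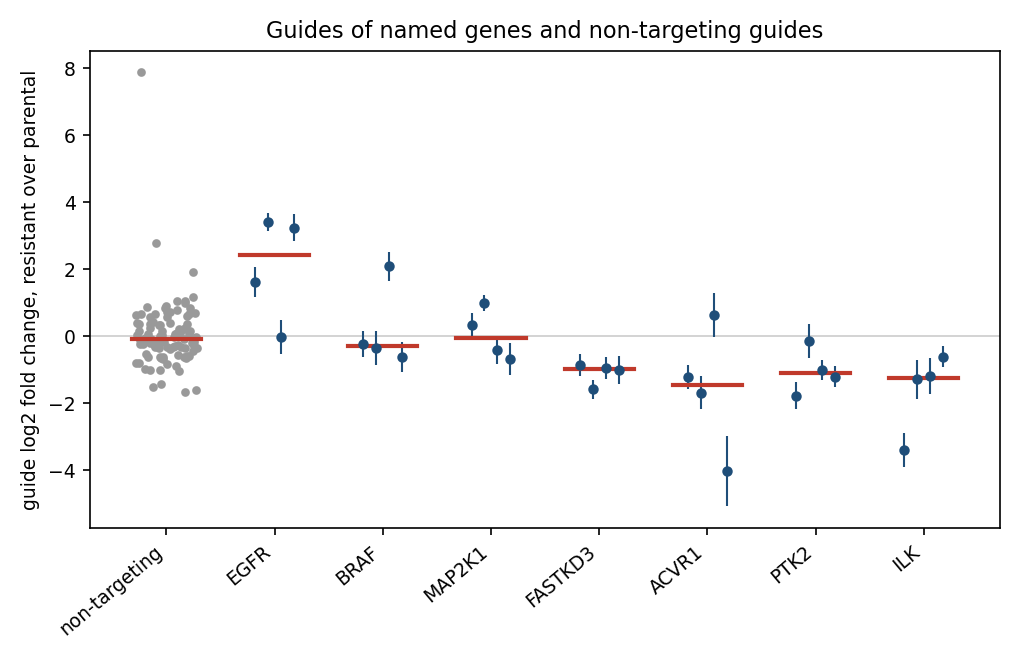
Points are guides, the y axis is the guide log2 fold change of resistant over parental cells, bars are standard errors from edgeR, and red lines are medians. The 100 non-targeting guides (grey) are drawn without bars. The median of EGFR lies at 2.44, those of BRAF and MAP2K1 at -0.29 and -0.04, and those of FASTKD3, ACVR1, PTK2 and ILK between -0.98 and -1.45.

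No gene was depleted in the resistant line at the threshold. The lowest rank aggregation adjusted p was 0.179, 45 genes had an unadjusted p under 0.05 where 38.15 are expected by chance, and edgeR on summed counts per gene called 67 genes lower. The 5 genes with the smallest p, none of which passed, were FASTKD3, which encodes a mitochondrial protein, ACVR1, a BMP type I receptor, PTK2, which encodes focal adhesion kinase, ILK, which encodes integrin-linked kinase, and CAMK2A, a calcium/calmodulin-dependent kinase best known from neurons. Their median log2 fold changes were -0.98, -1.45, -1.10, -1.24 and -0.996, with rank aggregation adjusted p values of 0.179, 0.206, 0.206, 0.284 and 0.372. In edgeR on summed counts all 5 were called lower, with adjusted p values of 4.17e-05, 0.00116, 0.000168, 0.000137 and 0.000168. That test also called sets of non-targeting guides, as given below. All 4 guides of FASTKD3, PTK2 and ILK had negative values, as had 3 of 4 guides of ACVR1 and CAMK2A. Average abundance was 529 ± 9.10 CPM per PTK2 guide in parental and 247 ± 6.84 in resistant cells, and 360 ± 0.763 and 152 ± 14.4 per ILK guide (SD, n = 2 each).

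In the list of SRC-family and focal adhesion kinases, 3 of 18 measured members fell when adjusted over the list alone, PTK2 and ILK among them. Adjusted over all genes, none of the 18 passed. SRC and YES1 stood at -0.28 and 0.17, and CSK, the inhibitor of SRC kinases, at -0.55. The members went both ways, 8 with a positive and 10 with a negative median, and the camera adjusted p of the list was 0.590.

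The other 3 of the 5 genes with the smallest p on the enriched side did not pass. They were PIK3R5, a regulatory subunit of the class IB PI3-kinase, SGK3, an AKT-related kinase, and PRKACG, a catalytic subunit of protein kinase A. Their median log2 fold changes were 0.87, 1.54 and 1.11, each with an adjusted p of 0.675. None of 16 measured genes of the PI3K-AKT-mTOR list passed by either adjustment. Medians were 1.11 for PDPK1, 0.78 for MTOR, 0.77 for AKT1, -0.08 for PIK3CA and 0.59 for PIK3CG, and the camera adjusted p of the list was 0.590. None of 28 members of the stress-activated MAPK cascades passed by either adjustment (camera adjusted p = 0.567). MAP3K7, which encodes the kinase TAK1, stood at 1.56, MAPK14, which encodes p38 alpha, at 0.75, MAP3K1 at 0.54 and MAP2K6 at -0.42.

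Core-essential kinases and cell-cycle kinases were not called as lists by camera. Of the 38 core-essential kinases, 24 had a positive and 14 a negative median, with a median of 0.21 over genes, and none passed singly by either adjustment. The unadjusted camera p was 0.0486 and the adjusted p 0.561 (0.683 with an estimated correlation). Against 10000 random gene lists of the same size, a test added after seeing the data, the mean shift of 0.30 had an adjusted permutation p of 0.0126, and that of the 26 cell-cycle and mitotic kinases, 0.33, an adjusted permutation p of 0.0266. The camera adjusted p of the cell-cycle list was 0.590 (0.683 with an estimated correlation). Examples were CDC7 at 2.04, BUB1B, a spindle checkpoint kinase, at 1.41, CDK1 at 1.25, PLK1 at 0.90, AURKC at 0.32 and AURKB at -0.31. The values of CDC7 and CDK1 rest in part on guides near 0 in the parental replicates. A CDC7 guide had 0.6 and 0.3 CPM there, and a CDK1 guide 0 and 0. The most abundant CDC7 guide had a log2 fold change of 1.18. In the replicate 1 and replicate 2 libraries the medians were 1.46 and 3.33 for CDC7, 0.49 and 1.81 for BUB1B and 0.64 and 0.08 for AURKC. The kinases of G1, CDK4 and CDK6, stood at -0.40 and 0.74. PLK1 stood at -0.21 once guides with a mean count under 100 were left out, and CMPK1 and TLK2, also in the core-essential list, stood at -0.48 and 0.74.

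The remaining 7 lists were not called by camera, with adjusted p values from 0.561 to 0.937, and none of their members passed when adjusted over all genes. Adjusted over the list alone, ACVR1 fell among the 12 TGF-beta and BMP receptor kinases, in which BMPR1B stood at -0.33, ACVR1C at -0.85 and AMHR2 at 0.75. No member of the other 6 lists passed that way. Among 16 LKB1-AMPK kinases, STK11, which encodes LKB1, stood at 0.01, PRKAA1, an AMPK catalytic subunit, at -1.38, MARK2 at -1.08, SIK1 at 1.01 and BRSK1 at 1.10. Among 15 Hippo kinases, LATS1 and LATS2 stood at 0.48 and 0.47, STK3 at -0.42 and MAP4K3 at -0.33. Of the 11 DNA damage kinases, PRKDC stood at 0.87, CHEK2 at 0.38 and SMG1 at -0.72. Of the 26 transcription and splicing kinases, DYRK2 stood at 1.28, CDK19 at 0.63, CLK4 at -0.59 and SRPK1 at -0.21. Of the 30 nucleotide and cofactor kinases, NME6 stood at 0.94, UCK1 at 0.42 and ADK at -0.72. Of the 45 tissue-restricted kinases, CAMK2A, named above, was also a member, LCK stood at -0.59, STK31 at -0.86 and TSSK6 at 0.42. Some medians hide a wide range over 4 guides. It was -1.41 to 10.9 for UCK1, -0.80 to 9.22 for SMG1, -0.54 to 8.98 for BRSK1 and 0.25 to 7.55 for TSSK6. The highest guides of UCK1, SMG1 and BRSK1 had 0 CPM in both parental replicates, and that of TSSK6 had 1.2 and 0.3. Fold changes from such counts are imprecise. Other ranges reached low, with -4.16 to 1.26 for LCK and -4.02 to 0.63 for ACVR1. The values of SRC, YES1, IGF1R, PIK3CA, STK11 and AURKC also changed sign when a single library was left out. The medians of CDK4, CDK6, UCK1, CHEK2, CMPK1, STK11, IGF1R, PIK3CA and YES1 differed in sign between the replicate 1 and the replicate 2 libraries, with 1.68 and -0.05 for CDK6 and 0.004 and -1.13 for CDK4. The camera direction differed in sign from a median over genes or over guides in the tissue-restricted, LKB1-AMPK, Hippo, transcription and TGF-beta lists.

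Single guides differed between the lines as often when they had no target as when they targeted a kinase. With edgeR, 301 of 3046 kinase guides passed (9.88%, exact 95% interval 8.84 to 10.997%), 167 lower and 134 higher in resistant cells. Of the 100 non-targeting guides, 10 passed (10%, exact 95% interval 4.90 to 17.6%), 7 lower and 3 higher, and Fisher's exact test of the 2 shares gave p = 1.00 (two-sided). The log2 fold changes had an SD of 1.05 in both sets, with 1 non-targeting guide at 7.87, and a median absolute deviation, scaled to match an SD, of 0.757 for kinase and 0.646 for non-targeting guides. Of all 311 guides called, 174 were lower and 137 higher, and scaling on the non-targeting guides gave 165 lower and 231 higher.

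**Figure D3:**
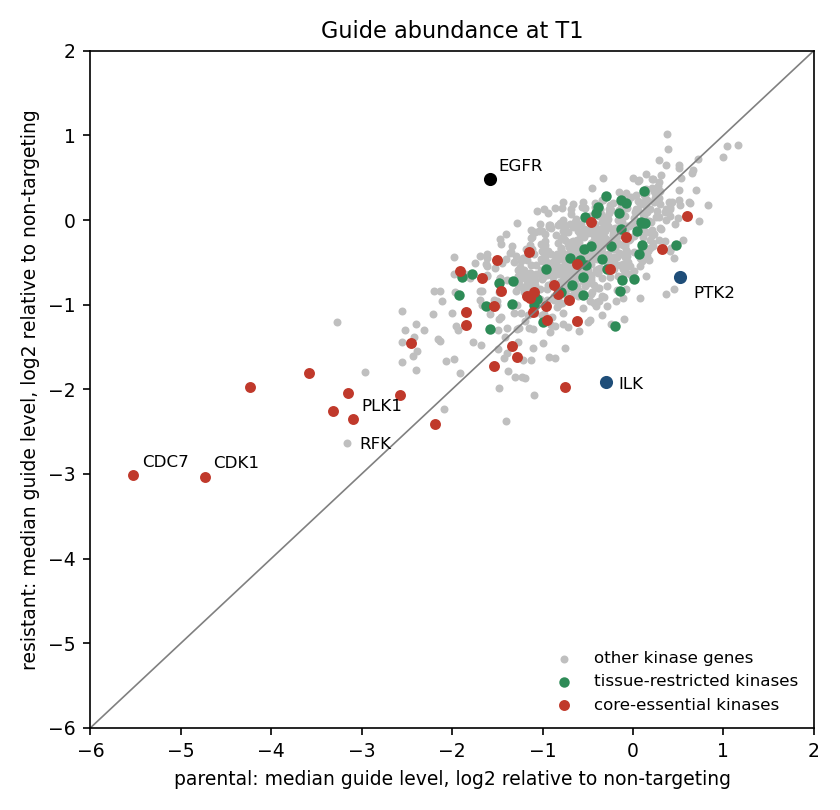
Points are genes, red for core-essential, green for tissue-restricted and grey for other kinases. The axes give the median guide level at T1 in parental (x) and resistant (y) cells, as log2 relative to the median non-targeting guide of the same library and averaged over 2 replicates, and the line marks equal levels. EGFR (-1.58 and 0.48), in black, lies above the line, and ILK and PTK2, in blue, lie below it.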

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

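The same 2 genes, EGFR among them, were called in the main analysis and in all 12 alternatives of scaling, count filter, guide test, replicate block and left-out library, and the count of genes stayed at 2 with an adjusted p under 0.10. EdgeR on summed counts per gene called 121 genes, 67 lower and 54 higher in resistant cells, and camera per gene called 0. The summed test also called 3 of 25 sets of 4 non-targeting guides (12%), beside 122 of 763 genes (15.99%) in the same fit. The count of guides was 311 in the main analysis and 768 with DESeq2, which also called 27 of 100 non-targeting guides. Leaving out a library gave 153 to 326 guides, with 183 without parental replicate 1 and 153 without parental replicate 2, while the genes stayed at 2 to 2 and the lists at 0 to 0. The fits without a replicate have 3 libraries, and the lone library of a line is assumed to vary like the other line. No cause of these changes in count was tested. With the replicate number as a block, 350 guides, 2 genes and 0 lists were called, so the block changed no call of a gene or list. Scaling on non-targeting guides moved the median of all guides from 0.02 to 0.12. No list passed with camera, with an estimated correlation or with fry, and 2 lists, the core-essential and the cell-cycle kinases, passed with shuffled genes. Of 876 values of the 73 named genes under 12 alternatives, 860 kept their sign and their side of the threshold. The other 16, all of genes called in none of these settings, changed sign. These 12 alternatives do not include summed counts per gene or camera per gene, whose calls differed as given above. DESeq2 gave no list result because camera does not use it. A fit of the compared groups alone is the main analysis, and alternatives for the comparisons with T0, or without a T0 library, were not run. Mean depth was 542 to 1242 reads per guide, and in simulated data at these depths with the line differences of the non-targeting guides 6% of 2-fold changes were recovered. This share may be too low, since replicate noise entered that simulation more than once. It may also be too high, since all guides of a changed gene received the same change.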

Other observations

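Knockouts that were scarce in both lines at T1 formed a group that the comparison between lines does not describe. In each library, a gene was taken as low when its median guide lay under the first percentile of 10000 random sets of 4 non-targeting guides, a rule chosen after the values were seen. By this rule 62 of 763 genes were low in both parental replicates, 46 in both resistant replicates and 23 in all 4 libraries, among them 9 of the 38 core-essential and 0 of the 45 tissue-restricted kinases. In parental cells 14 of the 38 core-essential and 5 of the 45 tissue-restricted kinases were low, and in resistant cells 13 and 0. The parental share of tissue-restricted kinases was thus no smaller than that of all 763 genes. Tissue-restricted guides also lay below non-targeting guides in parental (-0.48) and resistant cells (-0.42). A low level by this rule therefore does not by itself mark a knockout that was lost from a line. CDC7, CDK1 and PLK1 were among the 23, as was AURKA, the mitotic kinase Aurora A, at -4.24 ± 2.43 in parental and -1.98 ± 0.72 in resistant cells (log2 relative to non-targeting guides, SD, n = 2 each). The further examples were picked after their values were seen, and no function was tested for a surplus among the 23 genes. RFK, which makes the flavin cofactor FMN, stood at -3.16 ± 0.57 and -2.64 ± 0.003. NADK, which makes NADP, stood at -2.56 ± 0.29 and -1.67 ± 0.05. CLP1, a tRNA splicing factor, stood at -2.40 ± 0.06 and -1.77 ± 0.22. MAPK11, a p38 kinase, stood at -2.55 ± 0.02 and -1.44 ± 0.09 (SD, n = 2 each). Across the 763 genes, levels in the lines correlated at r = 0.71 (Spearman 0.66), and genes are not independent replicates. These levels include the share of each guide at transduction.

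Of the tests that follow, that of the non-targeting guides was chosen before the results were seen, and those of EGFR, in the form given here, and of the core-essential kinases were chosen after. EGFR guides were more abundant in the resistant line under sotorasib than in the parental line. A first explanation is abundance that differs between the lines for reasons other than the knockout. None of 100000 sets of 4 non-targeting guides reached the EGFR median of 2.44 (highest 1.97). The resulting bound of 0.0229 genes expected among 763 covers the error of the draws only. All sets came from the same 100 guides, so line differences of the size seen in these guides did not reach EGFR. The sets were not matched to EGFR in guide abundance. In parental replicates 1 and 2 the median non-targeting guide had 397 and 406 CPM, while EGFR averaged 134 CPM per guide in parental cells. How often other control guides, or guides as scarce as those of EGFR, would reach the EGFR median cannot be told, and the explanation is not excluded. A second explanation is weaker dropout of every dependency. On levels taken relative to the tissue-restricted guides, EGFR moved from -1.10 to 0.90. This lay 1.64 ± 0.27 (log2, combined SD without the error of the ratio) above the parental level times the core-essential ratio of the lines (0.669). A shift by that ratio was thus smaller than the EGFR rise. EGFR was tested because it rose, and its T1 levels include the share at transduction, so the comparison does not decide on weaker dropout. The 4 library genes nearest to its locus had a median of -0.11, inside the 5th to 95th percentile of random sets of 4 genes (-0.38 to 0.47). Their single values ran from -0.25 (PHKG1) to 0.48 (BAZ1B), and 4 genes are too few to exclude a copy-number difference. None is seen in their median, and a difference that is narrower or reaches only some of them stays open. The cause stays open, and the selected line and the drug cannot be told apart, since they changed together.

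Guides of core-essential kinases were less scarce in the resistant line. Library scaling does not account for this, since the gap between core-essential and tissue-restricted guides inside each library was smaller by 0.31 (log2) in resistant cells, against a largest replicate SD of 0.045. Random gene lists of the same size reached the mean shift in few draws (permutation p = 0.00089991 unadjusted, 0.0126 adjusted over 14 lists). These lists were drawn from all genes without matching guide abundance, and core-essential guides were scarce. Chance differences in abundance of single genes are therefore not excluded. The list was not called by camera (adjusted p = 0.561, or 0.683 with an estimated correlation) or by fry (adjusted p = 0.080). A candidate explanation is fewer cell divisions or less complete editing in the drug-treated resistant culture, and neither was tested.

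Non-targeting guides were called between the lines about as often as kinase guides. Their line difference in the replicate 1 libraries correlated with that in the replicate 2 libraries (r = 0.45, 95% interval 0.28 to 0.60, Spearman 0.47, n = 100 guides, permutation p = 1e-04, the smallest that 10000 permutations can give), although these pairs share no library. This is consistent with guide shares that already differed between the lines when the replicates were split, for example from separate transductions. Guide-level calls between the lines would then mix such differences with knockout effects, and agreement over the guides of a gene carries more weight than the p of a single guide.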
